A study of Mus musculus with 10 samples.

How the data were processed

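The series measured the DNA binding of bZIP domains on protein binding microarrays, which carry short duplex DNA probes on a glass slide. GST-tagged domains of mouse CREB1, CEBPB(V285A) and CREB1(A297V) were made in a cell-free expression system, per the labels' protocols, bound to 44K Agilent arrays and detected in the Cy5 channel. The probes follow a DeBruijn design, in which all short sequences occur in many contexts. Arrays were either left unmethylated or treated for 3 h with M.SssI, a methyltransferase that modifies the cytosine of CG dinucleotides. The labels put the 10 arrays in 5 groups of 2. These are CREB1 on unmethylated DNA, CEBPB(V285A) and CREB1(A297V) on unmethylated DNA, and CEBPB(V285A) and CREB1(A297V) on methylated DNA. Wild-type CEBPB and methylated arrays of CREB1 were not analysed here. Nothing in the labels says that the replicate arrays come from separate protein preparations, so the p-values measure the spread between arrays, which may be technical.

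Each array has a deposited table of spot intensities. Per the file headers these hold the median signal intensity and the median background intensity of each spot. The values are linear, reach 65528 and are not background-subtracted. Scanner settings and spot filters are not recorded. Each table holds 40330 probes with a variable region of 35 bases. The authors also deposited a matrix of 8-mer Z-scores, a score on a linear signal scale with a median of 0 in every column. Its columns were matched to arrays through the sample descriptions. A recomputation from signal minus background correlated with these scores at 0.981 to 0.996 per array, and one from signal alone at 0.862 to 0.994. The match was not exact, so the steps behind the authors' matrix are known only in part, and it was used as an alternative.

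The main score was computed from the spot signals. The log2 of each probe's median signal was lowered by the median over a window of 15 by 15 spots around it. For each 8-mer, merged with its reverse complement, the median was taken over all probes whose variable region holds it, with at least 8 probes required. All 32896 8-mers passed, with 15 to 42 probes each and a median of 34. The Z-score is this value minus the median over all 8-mers, divided by 1.4826 times the median absolute deviation, within each array. No background correction and no quantile normalization were applied, since binding may shift many probes in a single direction. Of the 8-mers, 20349 held no CG, 10762 held 1, 1702 held 2 and 83 held 3 or more.

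The number of arrays limits the precision. Median signal ranged from 345 to 1857 and the median ratio of signal to background from 1.79 to 5.10. Between 3 and 1543 probes per array lay below background, at most 3.83%. At most 7 spots per array reached 65000 or more, near the top of the scale. The unmethylated CREB1(A297V) arrays had the narrowest range: their strongest 8-mer lay 2.79 and 2.68 log2 units above the array median, against 4.73 to 6.05 on the other arrays. On the methylated CREB1(A297V) arrays 0% of probes lay at the same position as on the first array, against 100% on all others, so spatial effects fall on other probes there and cannot be told apart from the group.

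Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend). All 10 arrays entered with a coefficient per group, which leaves 5 residual degrees of freedom. Tests were two-sided and adjusted by Benjamini-Hochberg over all 8-mers, and an 8-mer was called at an adjusted p below 0.05. There were 7 comparisons. The trend was extrapolated at its upper end. For the 4 8-mers with a mean Z above 16 over all arrays (TGACGTCA, TTACGTAA, TGACGTAA and GTGACGTA) it expected an SD of 5.18 to 14.0, while their residual SD was 1.60 to 2.62. A missing call there carries little information. Where a difference of one of these 8-mers is printed, the adjusted p from its residual SD alone is given as well, an alternative chosen after seeing the data, and that of the fit without a trend. Differences of TGACGTAA are not printed. On simulated arrays made from the real means and spread, a planted Z difference of 4 was recovered for 96% (CEBPB(V285A) against CREB1), 100% (CREB1(A297V) against CREB1), 98% (methylation, CEBPB(V285A)) and 100% (methylation, CREB1(A297V)) of 50 8-mers. Those 8-mers were drawn at random and mostly bound weakly. Of the 32696 unchanged 8-mers, 5, 5, 6 and 11 were called. The simulated errors were independent between 8-mers, with the same SD in every group. Errors shared by overlapping 8-mers or by a whole array were not simulated. These few calls are therefore no measure of the false calls in the real data. In a test of the scoring, 10 of 10 planted 8-mers ranked first.

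Motif lists were tested with limma's camera, with the correlation within each list estimated, and adjusted over 105 tests (15 lists in 7 comparisons). Each list holds every 8-mer with a core on either strand. The cores are TGACGT (cAMP response element or CRE half-site with a CG centre), TGACGC, GACGCA or ACGCAA (CRE/C-EBP chimera), TTGCGC (C/EBP half-site with a CG centre), TTGCAT, TTGCAA or TTGCAC (C/EBP half-site without a CG centre), TGATGC, GATGCA or ATGCAA (C/EBP-ATF composite), TTACGT (PAR site) and TGACTCA (AP-1 site). Control lists were the E-box CACGTG, ETS CCGGAA, GATA AGATAA, SP1 GGGCGG and TATA TATAAA, and further lists held the 8-mers by their number of CG dinucleotides. The list without CG is tested against its complement, so a pass shows only a gap between both. The AP-1 list has 8 members and was described, not tested.

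The 8-mers named in the text follow a rule fixed before the data were examined. They are a panel of 20, the 5 with the highest mean Z in each group, the 5 highest and 5 lowest called differences per comparison, and the strongest and weakest variants of 3 seed sequences. The called differences had to have a mean Z of at least 3 in a compared group and no overlap between replicate arrays. The rule on overlap was not applied to the difference of both methylation effects. Counts among bound 8-mers take those with a mean Z of at least 3 in any compared group. Members that reach it in only 1 group have their direction fixed by this filter. An 8-mer and its reverse complement are the same item, and only one strand is printed. Alternatives tried were no local median adjustment, normexp background correction with an offset of 50, log2 of foreground over background, the mean over probes, a rank statistic, median-centred log2 scores, quantile normalization, at least 16 probes, the authors' matrix, no variance trend, only the arrays compared, a minimum Z difference of 1, the replicate number as a block, leaving out each array, camera with a preset correlation of 0.01, fry, shorter and longer lists of the highest 8-mers, 8-mers with or without CG, and probes with no CG outside the 8-mer. Camera tests a list against the other 8-mers, while fry tests it against no change, so their p-values answer different questions. Keeping flagged probes was planned too, but the tables carry no flag column.

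The array identifiers in the names of the deposited tables show that CREB1 and CREB1(A297V) on unmethylated DNA share an identifier, that CEBPB(V285A) on unmethylated DNA has another, and that both methylated groups share another one again. The comparison of CREB1(A297V) with CREB1 and that of both mutants on methylated DNA therefore lie within an identifier, and a block for it leaves them as they are. In the other comparisons the identifier and the group cannot be told apart. Figures were drawn with matplotlib 3.10.9, and scores were computed with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1.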

Results

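Binding of 3 bZIP DNA-binding domains was profiled on 10 protein binding microarrays, 2 per group. The bZIP family binds DNA as dimers, each monomer contacting a half-site of a short palindrome. CREB1 recognises the cAMP response element TGACGTCA, and CEBPB recognises the C/EBP site TTGCGCAA. CEBPB(V285A) and CREB1(A297V) each carry an amino acid substitution in the DNA-binding domain. The title of the series asks whether CEBPB(V285A) has binding preferences like those of CREB1. All values below are Z-scores of 8-mers within an array, given as mean ± SD with n = 2 arrays per group. Median spot signal ranged from 345 to 1857 and median signal over background from 1.79 to 5.10. Replicate arrays correlated across all 8-mers at 0.935 for CREB1, 0.969 and 0.973 for CEBPB(V285A) on unmethylated and methylated DNA, and 0.872 and 0.966 for CREB1(A297V). Correlations between profiles run across 8-mers, which overlap and are not independent replicates.

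On unmethylated DNA, CREB1 bound TGACGTCA most strongly, at a Z of 30.8 ± 2.42, a signal 28.5-fold the array median. The next 8-mers were GTGACGTA at 25.3 ± 2.35, TGACGTAA at 21.2 ± 2.64, GATGACGT at 20.5 ± 2.76 and TGTGACGT at 20.1 ± 2.95, all with the half-site TGACG. The half-site followed by other bases was bound as well, as in TGACGTGG at 17.9 ± 2.32. The C/EBP palindrome TTGCGCAA stood at 2.36 ± 0.374 and TTGCATAA at 1.58 ± 0.200. There were 884 8-mers with a mean Z of at least 3.

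CEBPB(V285A) had high Z-scores at the CRE sequences that CREB1 bound, though equal strength was not tested. In addition it bound C/EBP sequences that CREB1 hardly bound. Its strongest 8-mers on unmethylated DNA were TTACGTAA at 25.5 ± 0.0367, a PAR-type site, TGACGTAA at 24.3 ± 0.392, TGACGTCA at 23.2 ± 0.111, GTGACGTA at 21.1 ± 1.85 and ATTACGTA at 19.3 ± 1.02. TTGCGCAA reached 16.2 ± 0.875 against 2.36 ± 0.374 for CREB1, a difference of 13.8 ± 1.25 (SE, adjusted p = 4.35e-06), or 9.73-fold against 1.29-fold of the array median. The C/EBP sites without a CG followed. TTGCATAA was at 14.3 ± 0.261 against 1.58 ± 0.200 (adjusted p = 8.36e-07), TGATGCAA at 11.6 ± 0.698 against 2.88 ± 0.531 (adjusted p = 6.65e-06) and TTGCACAA at 4.46 ± 0.226 against -0.457 ± 0.0107 (adjusted p = 2.27e-06). ATTGCGCA was higher by 5.04 ± 0.585. TTGCGTAA and TTACATAA were higher by 11.7 ± 2.60 and 12.7 ± 2.36. The TTGCGTAA call was lost without any single array of the compared groups, with differences of 10.4 to 12.9. The TTACATAA call was lost without CREB1 replicate 1 or either CEBPB(V285A) array, with differences of 12.4 to 13.1.

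The panel of 20 fixed 8-mers gave 6 higher for CEBPB(V285A) than for CREB1, 0 lower and 14 not called. All 6 hold the C/EBP half-site TTGC. CRE half-sites did not pass the test. TGACGTGG stood at 15.8 ± 1.64 for CEBPB(V285A) and 17.9 ± 2.32 for CREB1, TGACGTTT at 11.4 ± 1.01 and 10.2 ± 1.96, and ATGACGTC at 16.6 ± 0.0326 and 18.3 ± 2.53. On the scale of signal over the array median CEBPB(V285A) was the higher at TGACGTGG (9.23-fold and 6.97-fold) and ATGACGTC (10.3-fold and 7.27-fold). TGACGTCA itself differed by -7.58 units (CEBPB(V285A) minus CREB1), with an adjusted p of 0.739 under the trend, 0.111 from its own residual SD and 0.00184 without a trend. TTACGTAA was 10.1 units higher, with adjusted p values of 0.669, 0.117 and 0.00206 in the same order. On the scale of signal over the array median the proteins stood at 26.3-fold and 28.5-fold for TGACGTCA. Among the 5 lowest called differences were AAAGAAAG, at -0.0372 ± 0.259 against 3.64 ± 0.524, and AACGGGGC, at 0.341 ± 0.0898 against 3.14 ± 1.15. CREB1(A297V), whose arrays share an identifier with CREB1, stood at 4.32 ± 0.508 and 3.82 ± 0.437 on these. TTTTACGT, which holds the PAR core, stood at 4.78 ± 0.441 against 7.08 ± 1.15 (adjusted p = 0.0425), a call lost without 7 of the 10 arrays, with differences of -3.11 to -1.48.

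**Figure D1:**
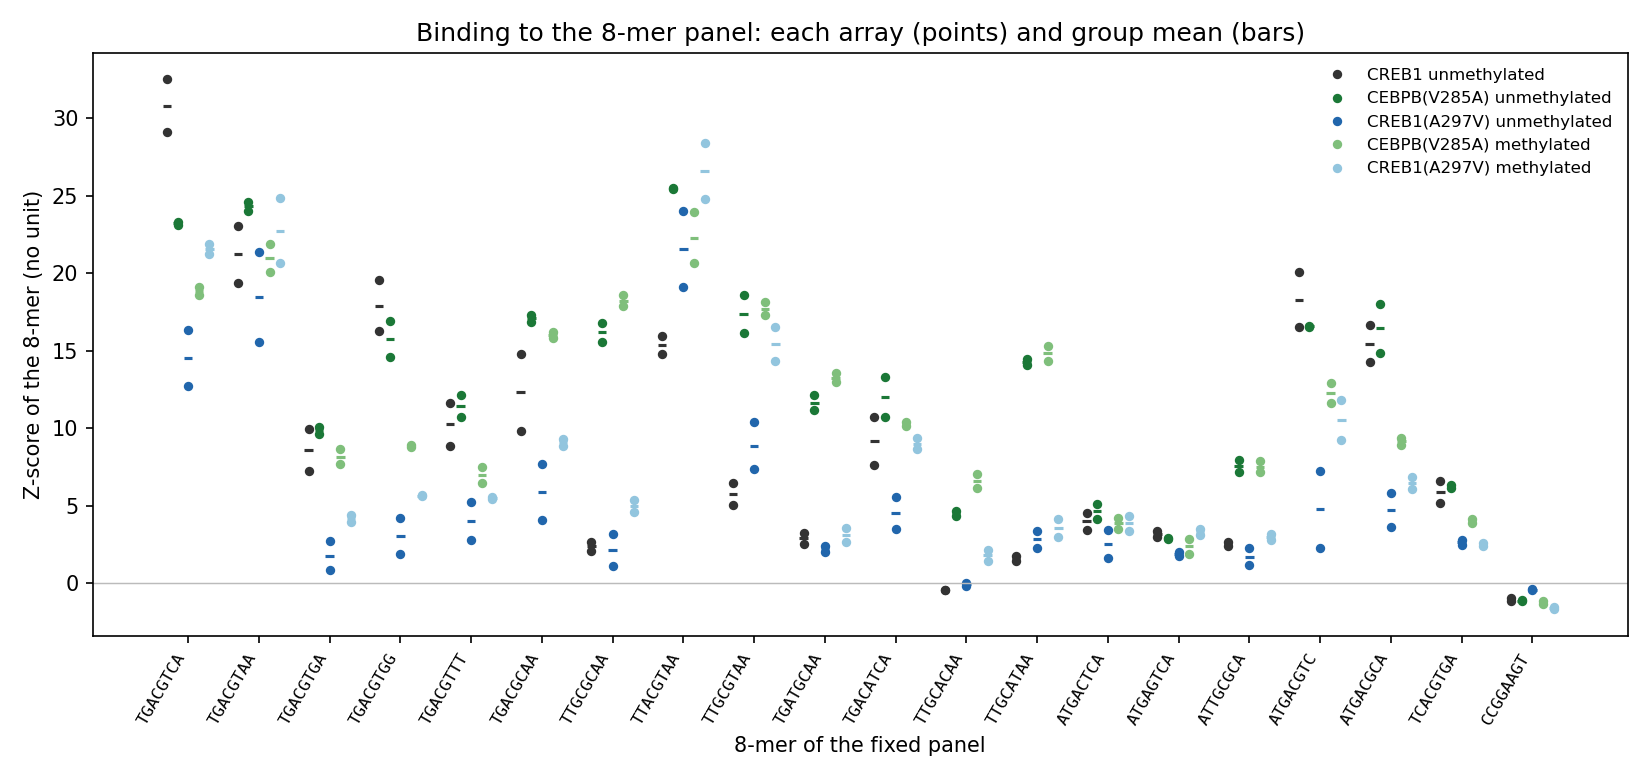
Z-score (y axis, no unit) of each of the 20 panel 8-mers (x axis) on every array (points, 2 per group) with the group mean (short bars), coloured by group. CEBPB(V285A) follows CREB1 at TGACGTGG (15.8 and 17.9) and stands far above it at TTGCGCAA (16.2 and 2.36), while CREB1(A297V) on unmethylated DNA stands at 3.04 and 2.12 on these.

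By motif list, the C/EBP half-site with a CG centre was higher for CEBPB(V285A), at a mean Z of 1.93 ± 0.0281 against 0.572 ± 0.161 for CREB1. Of its 48 members 21 were higher, 0 lower and 27 not called, and 30 were higher when adjusted over the list alone (camera, adjusted p = 0.0459). The C/EBP half-site without a CG centre was higher too, at 1.65 ± 0.0384 against 0.371 ± 0.0292. Of its 122 members 48 were higher, 1 lower and 73 not called, and 69 were higher and 2 lower when adjusted over the list alone (adjusted p = 0.0459). In the C/EBP-ATF composite list 38 of 128 members were higher and 2 lower, but the list did not pass (adjusted p = 0.114). The CRE/C-EBP chimera list had 28 of 128 higher and 2 lower (adjusted p = 0.523). Of the 48 members of the CRE half-site list 0 were called in either direction, with means of 13.2 ± 0.966 and 14.1 ± 2.03 (adjusted p = 0.827). Its sign turned under median-centred log2 scores, under foreground over background and with the authors' scores, and with normexp it went from -0.973 to -4.59. The PAR list stood at 9.27 ± 0.420 and 7.29 ± 1.08, with 3 members higher and 1 lower (adjusted p = 0.523, of opposite sign with normexp, as for the chimera list), and the 8 AP-1 8-mers at 2.22 ± 0.417 and 1.82 ± 0.496 with none called.

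Over all 8-mers, 2040 differed between CEBPB(V285A) and CREB1, 1207 higher and 833 lower. Of the 1281 8-mers with a mean Z of at least 3 in either group, 214 were higher and 28 lower. The mean profiles of both proteins correlated at r = 0.915 (Spearman 0.879), and at 0.861 over those 1281. Array pairs gave 0.884 to 0.906, against 0.935 and 0.969 between replicates. Of the 100 highest 8-mers 77 were shared, against 89 and 84 between replicate arrays and 0.304 for independent lists. For 8-mers with a CG the correlation was 0.948 and for those without 0.846. The count of called 8-mers fell to 225 without CEBPB(V285A) replicate 1 and reached 3574 without unmethylated CREB1(A297V) replicate 1, and with normexp correction 31.7% of calls were higher in place of 59.2%. The array identifier and the protein cannot be told apart here, and the list calls ended when any 1 of the 10 arrays was left out.

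CREB1(A297V) differed from CREB1, within a shared array identifier, at more 8-mers than CEBPB(V285A) did (6226 against 2040). No test compared both differences. The order of these counts turned with median-centred log2 scores, and their ranges with 1 array left out overlapped. CREB1(A297V) was lower at 46 of 48 8-mers with the CRE half-site. Its strongest 8-mers were TTACGTAA at 21.6 ± 3.47, TGACGTAA at 18.5 ± 4.09, TTACGACA at 14.9 ± 3.68, TGACGTCA at 14.5 ± 2.58 and ATTACACA at 12.9 ± 2.71. TGACGTGG fell from 17.9 ± 2.32 for CREB1 to 3.04 ± 1.66, a difference of -14.9 ± 1.70 (SE, adjusted p = 2.17e-05), or from 6.97-fold to 1.29-fold of the array median. These folds include background, and signal over background was 2.76 and 1.79 for CREB1(A297V) against 5.10 and 3.54 for CREB1. TGACGTTT and TGACGTGA were lower, with differences of -6.24 ± 1.16 and -6.81 ± 0.954. CGTGACGT, GTGACGTA, GTGACGTC and TGTGACGT were the other lowest called 8-mers, with differences of -15.9 to -14.3. The GTGACGTA call was lost without CREB1 replicate 2 and without either methylated CEBPB(V285A) array, with differences of -18.2 to -13.7 (adjusted p = 0.0204, 0.0379 from its own residual SD and 3.64e-05 without a trend). TGACGTCA differed by -16.3 units, with an adjusted p of 0.331 under the trend, 0.0327 from its own residual SD and 7.94e-06 without a trend.

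The 5 highest called differences for CREB1(A297V) were at 8-mers with TTAC or TGTC. ATTACACA stood at 12.9 ± 2.71 against 3.10 ± 0.652 for CREB1 (adjusted p = 0.000241), TTACCTAA at 12.2 ± 3.37 against 2.78 ± 0.246, TTACACAT at 10.9 ± 2.50 against 2.26 ± 0.438 and TGTCGACA at 10.8 ± 2.76 against 3.82 ± 0.817. TTACATAA was higher by 8.64 ± 2.36, a call lost without either CREB1 array, with differences of 7.65 to 9.64 over all arrays left out. The C/EBP 8-mers of the panel were not called. TTGCGCAA stood at 2.12 ± 1.47 against 2.36 ± 0.374, TTGCATAA at 2.83 ± 0.785 against 1.58 ± 0.200 and TGATGCAA at 2.22 ± 0.267 against 2.88 ± 0.531. Of the panel, 0 were higher, 8 lower and 12 not called.

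Across lists, 46 of 48 CRE half-site members were lower and 2 not called, the same numbers when adjusted over the list alone, with means of 4.31 ± 1.55 against 14.1 ± 2.03. With the estimated correlation of 0.762 between its members, the list did not pass (adjusted p = 0.192), while a preset correlation of 0.01 gave 2.60e-39. Against no change, fry gave 0.00364. The ETS control list, with a mean difference of only 0.260, gave a lower fry value of 0.0030, so this result does not single out CRE sites. All 26 E-box 8-mers were lower, over all 8-mers and adjusted over the list alone (list adjusted p = 0.114), and 23 of 48 PAR members (adjusted p = 0.386). The mean difference of the PAR list, -2.34, was -0.0864 with quantile normalization and -2.82 with normexp. Of the 122 C/EBP half-site members without a CG centre 19 were higher and 2 lower (adjusted p = 0.239), and of the 48 with a CG centre 0 were higher and 2 lower (adjusted p = 0.386). The list of 8-mers without CG passed against all others (adjusted p = 0.0459), with mean differences of 0.176 without CG and -0.397, -0.845 and -1.12 with 1, 2 and 3 or more. As scores are centred on the median of all 8-mers, only the gap between these sets is measured, not a rise of either. In all, 6226 8-mers differed, 2674 higher and 3552 lower, and of the 1248 with a mean Z of at least 3 in either group 300 were higher and 699 lower. The profiles correlated at 0.719 over all 8-mers (Spearman 0.811) and 0.125 over those 1248. Replicate arrays of CREB1 and CREB1(A297V) correlated at 0.935 and 0.872. Of the 100 highest 8-mers 18 were shared, against 89 and 80 between replicates. The CREB1(A297V) arrays had the narrowest range, with the strongest 8-mer 2.79 and 2.68 log2 units above the array median. The count of called 8-mers fell to 2564 without CREB1 replicate 2, and the list call ended without any 1 array.

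**Figure D2:**
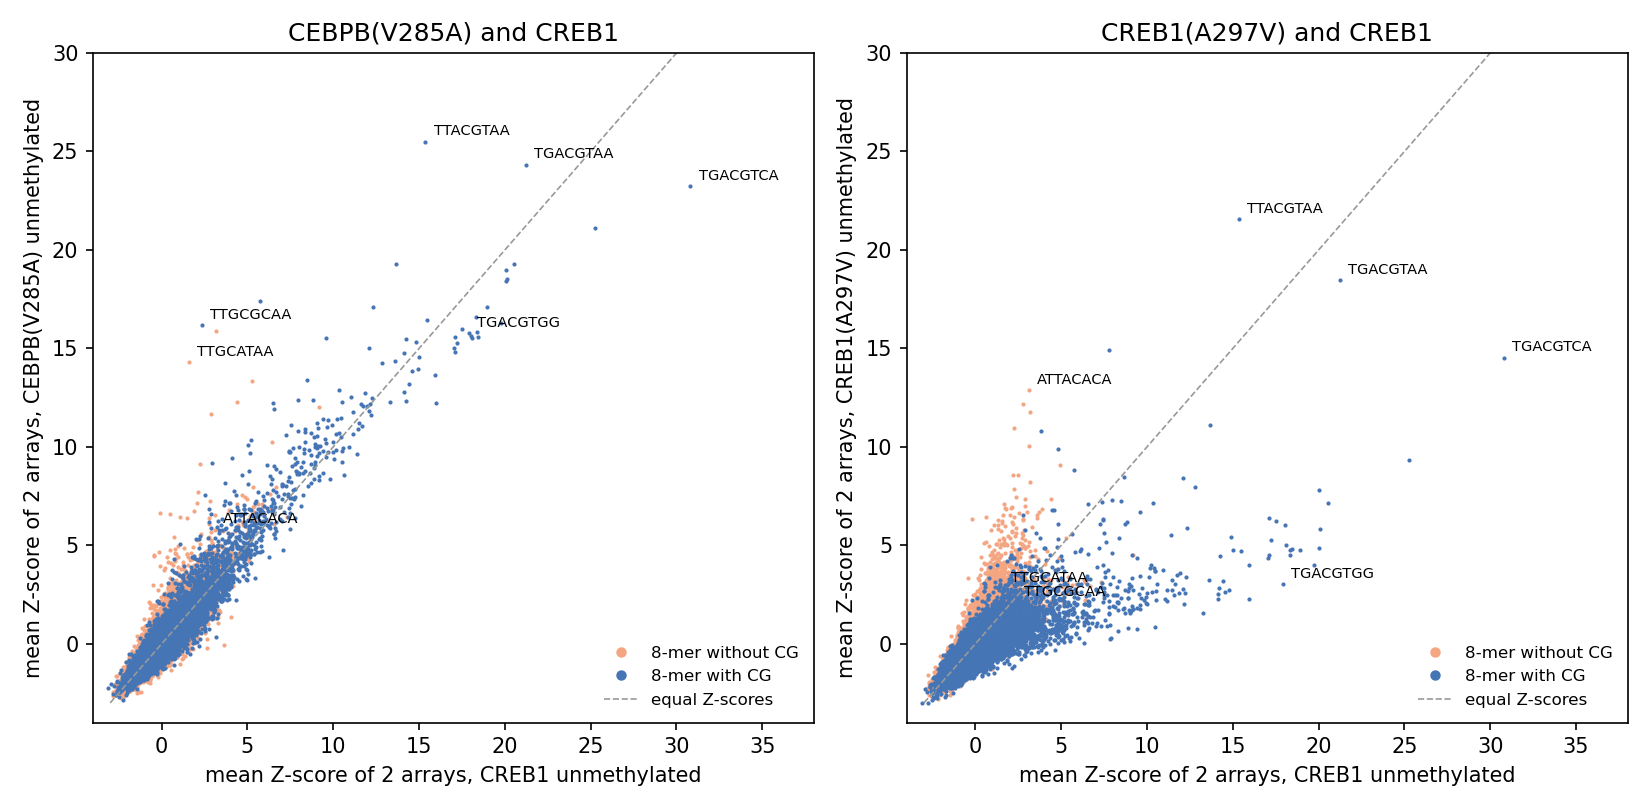
Mean Z-score of 2 arrays per 8-mer for CEBPB(V285A) (left, y axis) and CREB1(A297V) (right, y axis) against CREB1 (x axis), all on unmethylated DNA, with 8-mers coloured by whether they hold a CG and the dashed line at equal Z-scores. The left cloud follows the line (r = 0.915) with TTGCGCAA and TTGCATAA above it, and the right cloud bends below it at CRE half-sites such as TGACGTGG (3.04 against 17.9).

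Set against each other on unmethylated DNA, the mutants differed at both kinds of half-site. CEBPB(V285A) was higher at TTGCGCAA by 14.1 ± 1.25 (SE, adjusted p = 1.2e-06), at TTGCATAA by 11.5 ± 0.966 (adjusted p = 1.04e-06), at TGACGTGG by 12.7 ± 1.70 (adjusted p = 3.59e-05) and at GCTGACGT by 12.7 ± 1.31 (adjusted p = 4.39e-06). It was lower at TTACACAT (-8.68 ± 1.15), TGTCGACA (-8.31 ± 1.16), ATTACAAA (-6.78 ± 1.20) and TTACACAC (-6.53 ± 1.02). The strongest site of both, TTACGTAA, stood at 25.5 ± 0.0367 and 21.6 ± 3.47 (adjusted p = 0.845, 0.284 from its own residual SD and 0.0653 without a trend), and TGACGTCA at 23.2 ± 0.111 and 14.5 ± 2.58 (adjusted p = 0.605, 0.038 and 0.000151). As signal over the array median they stood further apart, at 36.1-fold against 6.66-fold and 26.3-fold against 3.58-fold. These folds include background, which lowers them where it is a larger share of the signal. Signal over background was 2.76 and 1.79 for CREB1(A297V) and 3.19 and 2.50 for CEBPB(V285A), so the wider gap is not a measure of binding alone. Of the panel 15 were higher for CEBPB(V285A), 1 lower and 4 not called.

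The C/EBP half-site list with a CG centre was higher for CEBPB(V285A) (31 of 48 members higher, 0 lower, 33 higher when adjusted over the list alone, adjusted p = 0.0459). Members of the CRE half-site list (45 of 48 higher, adjusted p = 0.229), the chimera list (114 of 128 higher, adjusted p = 0.192), the composite list (72 of 128 higher, 1 lower, adjusted p = 0.0697) and the PAR list (38 of 48 higher, adjusted p = 0.267) were called in numbers, but the lists did not pass with an estimated correlation. The mean difference of the PAR list, 4.33, shrank to 0.983 with quantile normalization and 1.62 with normexp. The list of 8-mers without CG passed against all others (adjusted p = 0.0459), with a mean difference of -0.110 against 0.409, 0.796 and 0.978 for 1, 2 and 3 or more CG, which again measures only the gap between the sets. In total 8409 8-mers differed, 4628 higher and 3781 lower. The count fell to 3682 without CEBPB(V285A) replicate 1, the list calls ended without any 1 array, and array identifier and protein cannot be told apart.

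The substitution series changed each base of 3 seed sequences in turn. From TGACGTCA, the best single change was the same for every group, TGACGTAA, at 21.2 ± 2.64 for CREB1, 24.3 ± 0.392 for CEBPB(V285A) and 18.5 ± 4.09 for CREB1(A297V) on unmethylated DNA. Of its 12 distinct variants, 10 had a mean Z of at least 3 for CREB1, 9 for CEBPB(V285A) and 4 for CREB1(A297V). The weakest were TGACTTCA at 1.17 ± 0.637 for CREB1 and TGACGGCA at 2.32 ± 0.758 for CEBPB(V285A) and 0.0295 ± 0.714 for CREB1(A297V). From TTGCGCAA, the best variant was TTGCGTAA in every group, at 5.74 ± 0.971, 17.4 ± 1.73 and 8.85 ± 2.14. The weakest were TTGCCCAA for CREB1 and CEBPB(V285A), at -1.35 ± 0.0678 and -0.361 ± 0.0453, and TTGCGCAG for CREB1(A297V), at -0.902 ± 0.462. The chimeric seed TGACGCAA stood at 12.3 ± 3.49 for CREB1, 17.1 ± 0.343 for CEBPB(V285A) and 5.86 ± 2.56 for CREB1(A297V). Of its 24 variants 11, 17 and 4 reached a Z of 3. Its weakest variant was TTGCGGCA for CREB1, at -0.348 ± 0.164, and TTGCTTCA for both mutants, at 0.0934 ± 0.353 and -0.525 ± 0.139.

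On methylated arrays CEBPB(V285A) had lower Z-scores at 23 of 48 8-mers with the CRE half-site, while none of its C/EBP 8-mers of the panel was called lower. TGACGTGG fell from 15.8 ± 1.64 to 8.83 ± 0.0848 (adjusted p = 0.0193), ATGACGCA from 16.5 ± 2.23 to 9.14 ± 0.294 (adjusted p = 0.0173) and TGACGTTT from 11.4 ± 1.01 to 6.97 ± 0.758 (adjusted p = 0.0254). These calls were each lost without 3 or 4 of the 4 arrays compared, with differences of -8.11 to -5.79, -8.89 to -5.73 and -5.18 to -3.74. CTACGTAG, CCTACGTA and ACTACGTA fell by 8.43 ± 0.975, 8.15 ± 0.879 and 6.98 ± 1.02. The E-box palindrome TCACGTGA fell from 6.22 ± 0.122 to 4.01 ± 0.166 (adjusted p = 0.0227), a call lost without any of the 4 arrays, with differences of -2.33 to -2.10. TTGCGCAA stood at 16.2 ± 0.875 and 18.2 ± 0.493 (adjusted p = 0.321), TTGCGTAA at 17.4 ± 1.73 and 17.7 ± 0.623 and TGACGCAA at 17.1 ± 0.343 and 16.04 ± 0.265 (11.1-fold and 17.8-fold of the array median). TTACGTAA and TGACGTCA were at 22.3 ± 2.32 and 18.9 ± 0.368 on methylated DNA, against 25.5 ± 0.0367 and 23.2 ± 0.111 (adjusted p = 0.898 and 0.845, 0.464 and 0.228 from their own residual SD, and 0.197 and 0.0347 without a trend). As signal over the array median both stood higher on methylated DNA, at 54.3-fold against 36.1-fold and 29.6-fold against 26.3-fold, so their direction depended on the scale. The highest called differences were at TTACATCG, which went from 1.20 ± 0.134 to 5.19 ± 1.05, CATGATTA (3.48 ± 0.637), TTACCTCA (3.42 ± 0.912), GTTACGCG, from 2.69 ± 0.226 to 5.89 ± 0.435, and TTGCATCG, from 0.884 ± 0.247 to 3.88 ± 0.445. CATGATTA and TTACCTCA hold no CG, and their calls were lost without 3 and 4 of the 4 arrays, with differences of 2.83 to 4.14 and 3.32 to 3.52. TTGCACAA, the only panel member called higher, rose by 2.12 ± 0.413, a call lost without 3 of the 4 arrays, with differences of 1.65 to 2.60.

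In the CRE half-site list 23 of 48 members were lower and 0 higher, 35 lower when adjusted over the list alone, and the mean went from 13.2 ± 0.966 to 8.47 ± 0.520 (adjusted p = 0.267, or 6.13e-22 with a preset correlation). The difference of -4.69 shrank to -2.14 with quantile normalization, with 17 members lower, and to -1.57 with normexp, with 3 lower. In the E-box list 14 of 26 were lower (adjusted p = 0.210) and in the chimera list 40 of 128 lower and 2 higher (adjusted p = 0.425). The mean difference of the chimera list, -1.39, was -0.679 with quantile normalization and -0.506 with normexp. In median-centred log2 scores, in log2 units, it was -0.0744. That of the PAR list, -0.879, changed sign in 4 of the other scalings. The C/EBP half-site lists had 7 of 48 higher with a CG centre (adjusted p = 0.205) and 25 of 122 without (adjusted p = 0.114), with 0 lower in both. The list of 8-mers without CG passed against all others (adjusted p = 0.0459), at a mean difference of 0.114, a measure of the gap to 8-mers with CG alone. Those with 1, 2 and 3 or more CG differed by means of -0.201, -0.389 and -0.558, with array pairs from -0.254 to -0.149, -0.495 to -0.284 and -0.681 to -0.436. Among bound 8-mers (mean Z of at least 3 in either group) 289 of 875 with a CG were lower and 32 higher, against 16 lower and 84 higher of 548 without. For members that reached 3 in only 1 group the direction is fixed by this filter. In all 2490 8-mers differed, 1262 higher and 1228 lower. The count fell to 122 without methylated replicate 1, the list call ended without any 1 array, and array identifier and methylation cannot be told apart.

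CREB1(A297V) had higher Z-scores on methylated DNA at many of its sites, with or without CG. ATTACTCA went from 7.44 ± 2.00 to 15.2 ± 1.28 (adjusted p = 5.36e-05), ATTACTAA from 8.58 ± 1.58 to 16.2 ± 1.04 (adjusted p = 4.9e-05), TTACCTAA from 12.2 ± 3.37 to 19.8 ± 1.39 (adjusted p = 0.004, a call lost in 6 processing alternatives) and TAATTACG from 6.06 ± 2.20 to 13.4 ± 2.02 (adjusted p = 0.000439). ATTACGCA rose by 8.03 ± 1.88, a call lost without methylated replicate 2, with differences of 5.86 to 10.2 over all arrays left out. TGACGTCA stood at 14.5 ± 2.58 and 21.6 ± 0.431 (adjusted p = 0.692, 0.0649 from its own residual SD and 0.00152 without a trend, or 3.58-fold and 19.3-fold of the array median), TTACGTAA at 21.6 ± 3.47 and 26.6 ± 2.54 (adjusted p = 0.802, 0.207 and 0.0287, or 6.66-fold and 38.6-fold), and TGACGTGG at 3.04 ± 1.66 and 5.64 ± 0.0575 (adjusted p = 0.287). The folds include background, which was a larger share of the signal on the unmethylated arrays (signal over background 2.76 and 1.79, against 5.09 and 5.03). The lowest called differences were at AACGGGGC, AAAGAAAG and AAAAGAAA, which fell by 4.60 ± 0.414, 3.64 ± 0.362 and 3.27 ± 0.368. Of the panel 3 were higher, 1 lower and 16 not called.

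None of the 15 lists passed for this comparison. In the PAR list 22 of 48 members were higher and 0 lower (adjusted p = 0.389), in the CRE half-site list 0 of 48 were called (adjusted p = 0.694) and in the AP-1 list 5 of 8 were higher. The mean difference of the PAR list, 2.89, shrank to 0.503 with quantile normalization and 0.574 with normexp. That of the CRE half-site list, 2.12, shrank to 0.334 and 0.357. At p below 0.05 before adjustment camera had 2 lists lower, ETS and SP1, and fry called 5 lists after adjustment. Mean differences were 0.0312, 0.0549, 0.00715 and -0.103 for 8-mers with 0, 1, 2 and 3 or more CG, with array pairs on both sides of 0 for each. Among bound 8-mers 319 of 608 without a CG were higher and 32 lower, and of 415 with a CG 217 were higher and 6 lower. Bound means a mean Z of at least 3 in either group, so 8-mers that reached it only on methylated DNA are higher by construction. On unmethylated DNA 362 without a CG and 190 with a CG reached it. Of these 296 and 170 had a higher mean Z on methylated DNA, called or not. Altogether 7095 8-mers differed, 3430 higher and 3665 lower. Signal over background was 2.76 and 1.79 on the unmethylated arrays of this protein and 5.09 and 5.03 on the methylated ones, under different array identifiers. The count fell to 2667 without methylated replicate 2, and with normexp correction 29.96% of calls were higher in place of 48.3%.

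**Figure D3:**
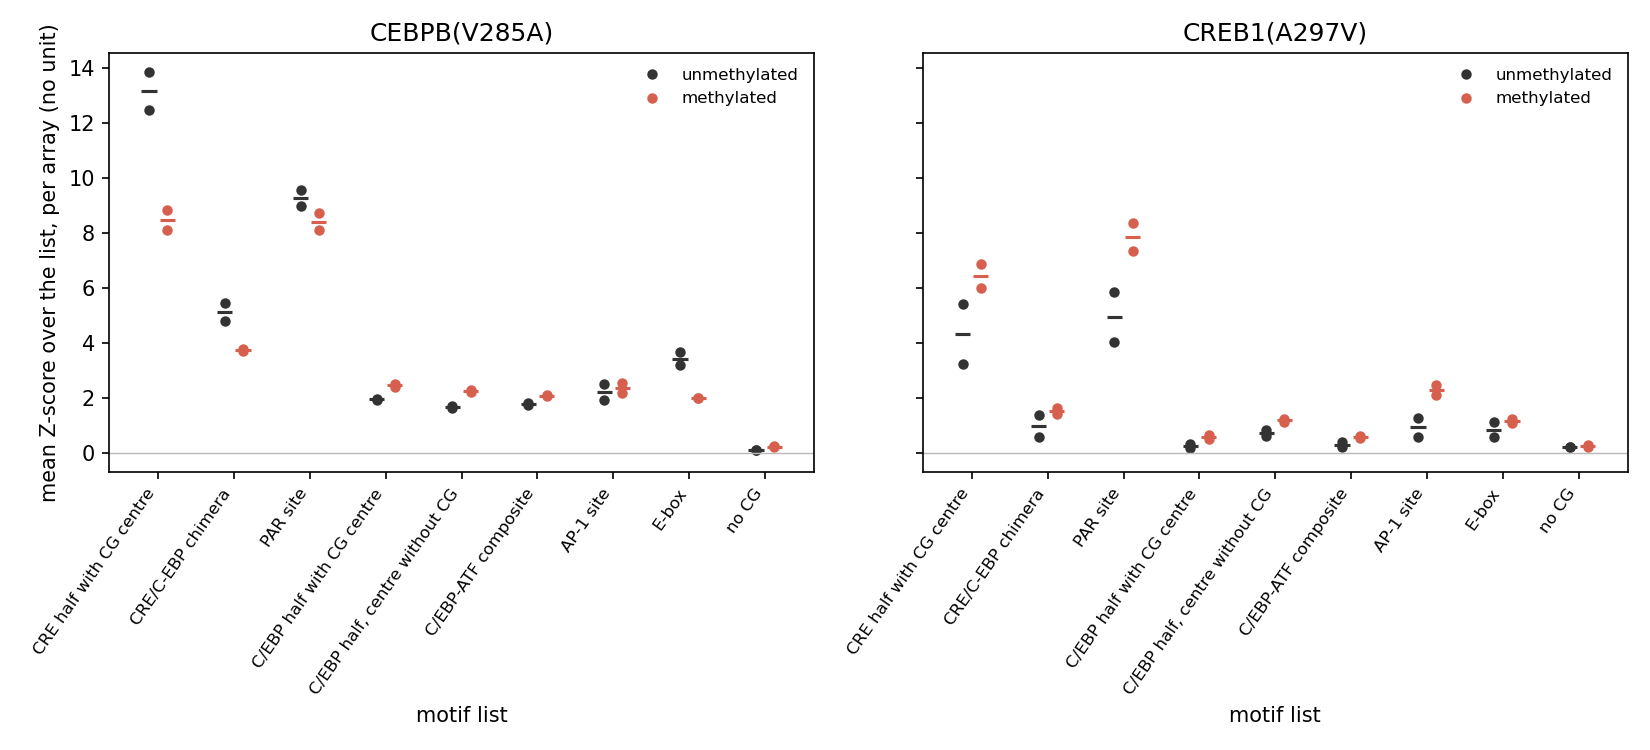
Mean Z-score over the members of 9 motif lists (x axis) per array (points) and per group (short bars) on unmethylated and methylated DNA, for CEBPB(V285A) (left) and CREB1(A297V) (right). The CRE half-site list goes from 13.2 to 8.47 for CEBPB(V285A) and from 4.31 to 6.43 for CREB1(A297V), and neither list passed the test. Both differences were smaller with quantile normalization (-2.14 and 0.334) and with normexp (-1.57 and 0.357).

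The difference between both methylation effects was tested directly. It passed for 1009 8-mers, 468 with a higher and 541 with a lower effect in CEBPB(V285A), and of the 1848 bound in any of the 4 groups for 31 higher and 253 lower. The lowest were CRE-type and CTACGTA-type sequences, TGATGACG with a difference of -10.9 ± 2.78 (SE), CTACGTAG with -10.2 ± 1.38, GATGACGC with -9.68 ± 2.27, TGACGTGG with -9.56 ± 2.40 and ACTACGTA with -9.12 ± 1.45. On unmethylated DNA CREB1(A297V) stood at 0.849 to 4.5 on these 8-mers, against 11.2 to 15.8 for CEBPB(V285A). As CREB1(A297V) had less room to fall, unequal starting levels and unlike methylation effects cannot be told apart at these sites. TTGCATCG, a C/EBP half-site with a CG at its end, was among the highest at 3.29 ± 0.427 (adjusted p = 0.00286). Of the CRE half-site list 13 of 48 members were lower, and 41 when adjusted over the list alone, but the list did not pass (adjusted p = 0.239, 7.62e-25 with a preset correlation). Against no change, fry gave 0.0338, and 0.0235 for the ETS control list. None of the 15 lists passed, with 1 list below 0.05 before adjustment (8-mers without CG). Without methylated CEBPB(V285A) replicate 1, 5 8-mers were called, and without unmethylated CREB1(A297V) replicate 2, 2646. The differences kept their sign without each array, but calls were lost: for TGATGACG without 7 arrays (-12.8 to -8.92), TGACGTGG 7 (-10.7 to -8.38), GATGACGC 6 (-11.9 to -7.48), ACTACGTA 4 (-10.2 to -8.06) and CTACGTAG 1 (-12.1 to -8.24), and for TTGCATCG without none. Among the other highest, GAAAAGAA was lost without 6 arrays (2.06 to 3.84) and in 8 alternatives, AACGGGGC without 3 (3.61 to 4.25), AAAAGAAA without 2 (3.45 to 3.85) and AAAGAAAG without 1 (3.47 to 4.19).

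On methylated DNA, within a shared array identifier, CEBPB(V285A) was higher than CREB1(A297V) at 5 of the 7 panel 8-mers with the half-site TTGC on either strand. TTGCGCAA was at 18.2 ± 0.493 against 4.99 ± 0.538 (adjusted p = 1.27e-06), TTGCATAA at 14.8 ± 0.685 against 3.58 ± 0.821 (adjusted p = 4.82e-07) and TGATGCAA at 13.3 ± 0.384 against 3.12 ± 0.639 (adjusted p = 2.93e-07), while TTGCGTAA, at 17.7 ± 0.623 against 15.4 ± 1.53, was not called (adjusted p = 0.623, or 0.43 from its own residual SD), nor was TGACGCAA, at 16.04 ± 0.265 against 9.07 ± 0.306 (adjusted p = 0.0566). The TGACGCAA difference gained a call in 8 alternatives and in 4 fits with an array left out, with differences of 6.75 to 7.18. TTATATAA and TTATATCA were higher by 8.21 ± 0.588 and 7.77 ± 0.456. The 5 lowest called differences were at TTACACAC (-13.2 ± 1.02), TTACACAT (-12.7 ± 1.15), ATTACAAA (-12.6 ± 1.20), ATTACTAA (-11.6 ± 0.949) and TTACCTAA (-11.1 ± 1.67). Neither TTACGTAA nor TGACGTCA was called. TTACGTAA stood at 22.3 ± 2.32 and 26.6 ± 2.54 (adjusted p = 0.86, 0.323 from its own residual SD and 0.0731 without a trend) and TGACGTCA at 18.9 ± 0.368 and 21.6 ± 0.431 (adjusted p = 0.908, 0.388 and 0.124). As signal over the array median CEBPB(V285A) was the higher at both (54.3-fold against 38.6-fold and 29.6-fold against 19.3-fold), so the direction depended on the scale. Of the panel 6 were higher for CEBPB(V285A), 0 lower and 14 not called.

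The C/EBP half-site list with a CG centre (33 of 48 members higher, 0 lower, 35 higher when adjusted over the list alone) and the composite list (70 of 128 higher, 0 lower, 79 when adjusted over the list alone) were higher for CEBPB(V285A), each with an adjusted p of 0.0459. The C/EBP half-site list without a CG centre had 45 of 122 higher and 4 lower (adjusted p = 0.114), the chimera list 68 of 128 higher (adjusted p = 0.239), the CRE half-site list 9 of 48 higher (adjusted p = 0.583) and the PAR list 10 of 48 higher and 0 lower (adjusted p = 0.749). Over all 8-mers 4027 differed, 2221 higher and 1806 lower. The count fell to 1094 without methylated CREB1(A297V) replicate 2, and the list calls ended without any 1 array. The probe layout of the methylated CREB1(A297V) arrays differed from that of all others, so that layout and protein cannot be told apart here. By camera the control lists ETS, GATA, SP1 and TATA passed in none of the 7 comparisons, with lowest adjusted p values of 0.0632, 0.239, 0.161 and 0.417. By fry, against no change, ETS passed in all 7 (adjusted p of 0.000694 to 0.0338). SP1 did so for methylation in both mutants (0.0471 and 0.00566) and TATA for that in CREB1(A297V) (0.0439). GATA did so for both mutants on methylated DNA (0.0138). The E-box control did not pass by camera either (lowest 0.114). At a mean Z of 3.61 for CREB1 and 3.41 for CEBPB(V285A) on unmethylated DNA, this list was no unbound control. Of its 26 members 24 were higher for CEBPB(V285A) than for CREB1(A297V) on unmethylated DNA and 0 lower.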

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

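The tests of the 8-mers made of A and G alone, of 8-mers matched in Z and of the array run at the CRE half-site were chosen only after the results had been seen. Results were picked out because an effect of methylation differed between both mutants in a direct test. There were 1009 such 8-mers. Among the named ones the effect in CEBPB(V285A) was below that in CREB1(A297V) for TGATGACG (-10.9), CTACGTAG (-10.2), GATGACGC (-9.68), TGACGTGG (-9.56) and ACTACGTA (-9.12). On these CREB1(A297V) started from a Z of only 0.849 to 4.5 on unmethylated DNA and had less room to fall. The effect in CEBPB(V285A) was above for AACGGGGC (3.93), AAAGAAAG (3.83), AAAAGAAA (3.65), TTGCATCG (3.29) and GAAAAGAA (2.95), of which GAAAAGAA lost its call without 6 arrays and AACGGGGC without 3. Without methylated CEBPB(V285A) replicate 1 only 5 8-mers were called, and with the residual SD of each 8-mer alone 3 were.

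The first pattern is the lower Z of CEBPB(V285A) at CRE half-sites on methylated arrays, where the mean over 48 8-mers went from 13.2 to 8.47, a difference of -4.69 (-5.74 to -3.64 over array pairs). Its size depended on the scale, at -2.14 (-2.30 to -1.97) with quantile normalization and -1.57 (-2.11 to -1.02) with normexp, where only 3 of the 48 were called. In median-centred log2 scores it was -0.483 (-0.707 to -0.259). The log2 range of the methylated arrays was not narrower, with the strongest 8-mer 6.05 and 5.48 above the median against 5.26 and 5.09. The divisor of the Z-score was larger, at 0.253 and 0.265 against 0.206 and 0.200. A narrower range of Z would lower 8-mers of the same Z alike. For 40 of the 48 CRE 8-mers there were 8-mers without CG within 1 unit of the same unmethylated Z. These differed by -0.209 (-0.752 to 0.333) where the CRE 8-mers differed by -4.32. This argues against a narrower range of Z as the whole cause, although only 8 of the 216 matched 8-mers had a Z of at least 8. A loss of TGAC half-sites in general was to be tested on all bound TGAC 8-mers without CG, which differed by -0.641 (-0.948 to -0.334), but they started from a mean Z of 4.61 and had less room to fall. TGAC 8-mers without CG matched in Z, available for 27 of the 48, differed by -1.82 (-2.48 to -1.16) against -3.77, and only 3 of these 89 had a Z of at least 8. A general loss of TGAC sites may therefore have a part in the pattern. CREB1(A297V) differed by 2.12 (0.591 to 3.66) at the same 48 8-mers, or by 0.334 with quantile normalization and 0.357 with normexp. Its unmethylated arrays do not share an identifier with those of CEBPB(V285A), so this rise does not exclude an effect of the array run. Methylation of the central CG, a general loss of TGAC sites and the array run cannot be told apart.

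The next pattern is the rise of CREB1(A297V) on methylated arrays at 362 bound 8-mers that hold no CG (mean 1.53, with a higher mean Z for 296, called or not). Both tests were planned before the result was seen. If methylated CG elsewhere on the probe drove it, probes with no CG outside the 8-mer would show less than 0.5 of the rise, but there it was 1.33 (0.707 to 1.95) against 1.39 over all probes for the same 283 8-mers. A wider signal range on the methylated arrays would stretch the profile and keep its order. The correlation of methylated and unmethylated Z over these 8-mers was 0.860 (0.718 to 0.897 over array pairs), below the 0.869 between replicate arrays but within the spread over array pairs. The low signal over background of the unmethylated CREB1(A297V) arrays may account for the rise, but the wider range and a change in binding cannot be told apart.

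The last pattern concerns 8-mers such as AAAGAAAG and AAAAGAAA, at 3.64 and 4.05 for CREB1. It was examined over all 8-mers made of A and G alone, G-rich ones included. Their mean for CREB1 lay far below these values, so the set describes itself more than these 8-mers. AACGGGGC is not part of it. The 256 8-mers made of A and G alone stood at a mean of -0.254 for CREB1 and 0.0248 for CREB1(A297V) on unmethylated DNA, against -0.725 for CEBPB(V285A). On methylated DNA they stood at -0.721 for CEBPB(V285A) and -0.669 for CREB1(A297V). CEBPB(V285A) minus CREB1 was -0.471 on unmethylated DNA. If this came from CEBPB as a protein, it would recur on methylated DNA. There CEBPB(V285A) minus CREB1(A297V) was -0.0526 (-0.188 to 0.0831). This cannot decide the question, since CREB1(A297V) takes the place of CREB1 there. CEBPB(V285A) hardly moved (-0.725 and -0.721), while CREB1(A297V) went from 0.0248 to -0.669. If the array run were the source, CREB1(A297V) and CREB1, which share an identifier, would differ by less than 0.5 of the gap. They differed by 0.279 (0.205 to 0.353) in the other direction, which is more than that for the mean and less for the nearest array pair. The array run and an effect of each protein and DNA state cannot be told apart here.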

How the results depend on the processing

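The numbers of called 8-mers depended strongly on the processing, and the cause was not tested. They are given in the order CEBPB(V285A) against CREB1, CREB1(A297V) against CREB1, both mutants on unmethylated DNA, methylation in CEBPB(V285A), methylation in CREB1(A297V), the difference of both effects, and both mutants on methylated DNA. The values to compare with are 2040, 6226, 8409, 2490, 7095, 1009 and 4027. No local median adjustment gave 643, 3530, 4865, 447, 2681, 277 and 1560. Foreground over background gave 701, 3797, 5072, 617, 2698, 272 and 1588. The authors' scores gave 721, 3863, 5033, 921, 2920, 602 and 2078. The mean over probes gave 6570, 14782, 17269, 7179, 11482, 4758 and 11412. The rank statistic gave 5952, 11823, 15510, 8037, 13825, 4075 and 9588. Median-centred log2 scores gave 4393, 3599, 10389, 10025, 9980, 2677 and 10066.

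Normexp changed the count of the methylation effect in CEBPB(V285A) to 1635, and quantile normalization, at least 16 probes and a fit without trend left all 7 near the first values. With only the arrays compared, the 2nd and the last 4 counts were 2518, 7696, 4605, 1798 and 8787. A Z difference of at least 1 left 4012, 5021, 1567 and 3925 in the 2nd to 5th comparison. The residual SD of each 8-mer alone, an alternative added after the data were seen, left 267, 1392, 3710, 21, 2435, 3 and 1050.

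The share of higher calls moved by more than 10 points in several settings. For CEBPB(V285A) against CREB1 it was 59.2%, and 79.2% with no local adjustment, 31.7% with normexp, 72.8% with foreground over background and 80.6% with the authors' scores. For CREB1(A297V) against CREB1 it was 42.9%, and 29.4% with median-centred scores and 32.6% with the authors' scores. For both mutants on unmethylated DNA it was 55.04%, and 43.7% with normexp and 71.1% with the authors' scores. For methylation in CEBPB(V285A) it was 50.7%, and 23.3% with no local adjustment, 66.5% with normexp and 32.9% with foreground over background. For methylation in CREB1(A297V) it was 48.3%, and 29.96% with normexp and 61.7% with the authors' scores. For the difference of both effects it was 46.4%, and 16.6%, 85.6%, 21.0% and 17.6% with no local adjustment, normexp, foreground over background and the authors' scores. For both mutants on methylated DNA it was 55.2%, and 68.2% with normexp.

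The numbers of lists called were 2, 1, 2, 1, 0, 0 and 2. Normexp, the mean over probes, the rank statistic and only the arrays compared left 0 in every comparison. Median-centred scores gave 3, 3, 5, 3, 1, 0 and 3. Quantile normalization gave 2, 2, 3, 1, 1, 0 and 3, foreground over background 3, 1, 3, 2, 0, 1 and 3, and the authors' scores 2, 1, 3, 2, 0, 0 and 3. A preset correlation of 0.01 gave 6, 12, 12, 12, 8, 11 and 13 lists, and fry gave 4, 11, 11, 8, 5, 4 and 6.

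With the replicate number as a block, 2291, 6581, 8832, 2801, 7570, 1345 and 4364 8-mers and 0 lists in every comparison were called. The residuals of replicate numbers correlated between groups from -0.213 to 0.333, so the numbers do not pair the arrays across all groups and this block is given here only. The highest value was that of CREB1 and CREB1(A297V) on unmethylated DNA, which share an array identifier. A pairing between these groups is therefore not excluded. Both methylated groups, which share an identifier too, gave -0.00169.

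The correlation of CEBPB(V285A) with CREB1 (0.915) was 0.903 with no local adjustment, 0.904 with normexp, 0.902 with foreground over background, 0.930 with ranks and 0.851 with the authors' scores. It was 0.846 over 8-mers without CG and 0.948 over those with CG. That of CREB1(A297V) with CREB1 (0.719) was 0.818 with ranks and 0.519 with the authors' scores. Of the 50 highest 8-mers 39 were shared by CEBPB(V285A) and CREB1, and 169 of a list 4 times as long. The mean methylation effect of CEBPB(V285A) at 8-mers with CG less that at those without (-0.343) was -0.283 with normexp and -0.538 with the authors' scores, and was not computed for ranks and median-centred scores. Over probes with no CG outside the 8-mer it was -0.306, and for CREB1(A297V) -0.0621 in place of 0.0162. Differences called in the substitution series (21) numbered 38 with median-centred scores and 8 with the residual SD alone.

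Of 216 values of named 8-mers, 8 changed sign in some setting, 1 of them in 2 settings, with the test passing in either setting. With normexp, ATGACGCA and TCACGTGA were lower for CEBPB(V285A) than for CREB1 (-4.23 and -2.30), and ATTACACA on methylation of CREB1(A297V) was at -0.874, and at -1.01 with quantile normalization. With ranks, TCACGTGA on methylation of CREB1(A297V) was at 0.0514, and TTGCACAA for the difference of both effects at -0.0763. With median-centred scores, TGACGCAA and ATTGCGCA rose on methylation for CEBPB(V285A) (0.683 and 0.405). With quantile normalization, TTGCATAA for the difference of both effects was at 4.32.

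Leaving out 1 array gave 225 to 3574, 2564 to 6767, 3682 to 9286, 122 to 4333, 2667 to 8048, 5 to 2646 and 1094 to 5745 called 8-mers and 0 lists throughout. The correlation of CEBPB(V285A) with CREB1 ranged from 0.891 to 0.915, the shared 8-mers from 74 to 80, the CG effect from -0.387 to -0.299 and, for CREB1(A297V), from -0.0851 to 0.118, and the substitution series from 9 to 24. Of 2160 fits of a named value (216 values, 10 arrays left out) 2001 stayed on the same side of the threshold, 39 gained a call and 120 lost it. Keeping flagged probes was not run, since no flag column exists.

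Among calls printed for methylation, TTACCTAA in CREB1(A297V) was lost with normexp, the mean over probes, ranks, quantile normalization, only the arrays compared and the residual SD alone. ATTACGCA was lost in 4, ATTACTCA in 3 and ATTACTAA in 2 of the alternatives. In CEBPB(V285A) TCACGTGA was lost in 6, and TGACGTGG, TGACGTTT, ATGACGCA and TTACCTCA in 4 each. For the difference of both effects TGATGACG was lost in 5, GATGACGC in 4 and TGACGTGG in 3. On unmethylated DNA TTTTACGT was lost in 7 and TTGCGTAA in 3 against CREB1 for CEBPB(V285A), and GTGACGTA and GTGACGTC in 3 each for CREB1(A297V). The call of GAAAAGAA for the difference of both effects was lost in 8. The mean difference of the CRE half-site list on methylation of CEBPB(V285A) (-4.69, with 23 of 48 members lower) was -2.14 with 17 lower under quantile normalization, -1.57 with 3 lower under normexp, -4.79 with 24 lower under foreground over background and -24.0 with 18 lower for the authors' scores. Median-centred log2 scores had 29 lower.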

Other observations

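Palindromes and pairs of half-sites were compared between groups, a choice made after the values had been seen. Among the 256 palindromes of a 4-base half-site, CREB1 bound those of TGAC (TGACGTCA, 30.8), TTAC (TTACGTAA, 15.4) and CTAC (CTACGTAG, 10.5) most. CEBPB(V285A) bound TTAC (25.5), TGAC (23.2) and TTGC (TTGCGCAA, 16.2), so that the half-sites of CREB1 and of C/EBP ranked next to each other. CREB1(A297V) on unmethylated DNA bound TTAC (21.6), TGAC (14.5), TGTC (TGTCGACA, 10.8) and GTAA (GTAATTAC, 9.09). In pairs, TGACATAA reached 13.4 for CEBPB(V285A) against 5.28 for CREB1 and 5.38 for CREB1(A297V), and TTATATAA 6.66 against -0.109 and 1.25. TTAC followed by any 4 bases without CG (153 8-mers) had a mean Z of 0.891 for CREB1, 1.53 for CEBPB(V285A) and 2.71 for CREB1(A297V), and 2, 18 and 52 of them had a Z of at least 3. On methylated DNA the means were 2.09 for CEBPB(V285A) and 3.80 for CREB1(A297V), with 31 and 71 of at least 3. No test was run on the rankings or on the means over sets. The single 8-mers were part of the tests over all 8-mers, and some of those results are printed above.

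Across array pairs the correlation of CREB1(A297V) with CREB1 spanned 0.597 to 0.746, more than the 0.884 to 0.906 of CEBPB(V285A) with CREB1. The replicates of CREB1(A297V) on unmethylated DNA correlated least (0.872), and replicate 2 had the lowest signal over background of all arrays (1.79). The profile of CEBPB(V285A) on methylated DNA shared 45 of the 100 highest 8-mers with CREB1 on unmethylated DNA, against 77 on unmethylated DNA, but no CREB1 array on methylated DNA was analysed here.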
